A study of Mus musculus with 6 samples.

How the data were processed

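Expression was measured in 393P cells, a mouse line whose name some of the labels write as 9393P. The cells carried either AC9 or the empty vector as a stable transfection, and each group held 3 samples. Per the labels' protocols, the cells grew in RPMI with serum, were transfected with jetPRIME and selected with puromycin or G418. Which drug was used for which group is not given in the sources used here. Total RNA was hybridised to Affymetrix Clariom S arrays, 1 array per sample, per the labels' protocols.

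The values used were the deposited log2 intensities per probe set, made with RMA per the submitters' processing notes. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set. The software that ran it, its version, the summary level and the genome build are not given in the sources used here, so no genome coordinates are printed. The unit was checked against the values, which lay on a log scale. All 6 columns of per-sample values matched a sample by name.

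Each array held 28846 probe sets, of which 22206 were not controls. GEO's annotation of the platform gave 19572 of these exactly 1 gene symbol, gave 0 several symbols, and left 2634 unnamed here. All 19572 were matched by gene number to a RefSeq gene table of the assembly GRCm38.p6, which changed 0 symbols. That table was used only for names and for the order of neighbouring genes. For 55 genes with several probe sets, the probe set with the highest mean over the 6 arrays was taken, which left 19505 genes. The controls comprised 23 background probe sets, 5222 negative and 1324 positive control probe sets, 63 ERCC probe sets and 8 other spike-in probe sets. The 90th percentile of the negative controls, averaged over the arrays, was 6.06 and served as a bound for dim signals. For a named gene with 1 group under it, the fold is given as a lower limit, and with both groups under it no size is given.

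AC9 was compared with VECTOR with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, two-sided). The deposited values were used as given, with no further normalization and no filter on dim genes. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05 and, for a separate count, a change of at least 2-fold. Standard errors are those of the limma fit, and SD is the standard deviation over 3 arrays. Nothing in the labels says whether the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

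25 gene lists were tested with camera from limma at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists; a list needed at least 8 measured members. They covered cAMP signalling components, CREB-responsive genes, epithelial identity and junctions, mesenchymal identity, integrins and focal adhesion, collagens and laminins with their modifying enzymes, matrix proteases and inhibitors, Golgi and secretory vesicle traffic, the G2/M cell cycle, and DNA replication and S phase. Further lists held interferon-stimulated genes, MHC class I antigen presentation, cytokines with chemokines and NF-kB targets, ERK pathway output, p53 target genes, hypoxia response and glycolysis, and the unfolded protein and amino acid stress response. The others held cholesterol synthesis, NRF2 and glutathione detoxification, YAP and TGF-beta responsive genes, lung epithelial lineage, leukocytes, endothelium and fibroblasts, ribosomal proteins, and oxidative phosphorylation. Members were counted after adjustment over all genes and after adjustment over the list alone. The set test was repeated with a correlation estimated per list.

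Genes were named by a rule. It took Adcy9, then the 12 genes with the largest positive and the 12 with the largest negative change among genes past the threshold whose groups did not overlap, leaving out predicted or unnamed genes. From each list it took up to 4 members past the threshold with the largest absolute change, or, where none passed, the 2 with the smallest p as values only. The rule gave 109 genes. The groups, the tests, the lists, this rule and all but 2 of the alternative settings were set before the data were examined. Named genes outside the rule are said to have been chosen after their values were seen.

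The alternative settings were an intensity-trended robust prior, a repeated quantile normalization, centring each array on its median, leaving out genes under the 40th percentile of mean level, the mean of a gene's probe sets, all probe sets without a choice per gene, array weights, the replicate number as a block, each array left out in turn, an adjusted p of 0.01, a 1.5-fold size threshold, an estimated correlation, and the fry test. Leaving the G2/M genes out of the other lists, and out of families of genes sharing a symbol stem, was added after seeing the data. The tests were also run on the 10 splits of the 6 arrays into 3 and 3. Chromosomes were taken from the probe set names; neighbouring genes were taken in blocks of 20, and gene density was counted within 1 Mb to each side, with 2000 bootstrap draws for the error of a corrected median and 2000 random orders of the genes of chromosome 18 for the blocks.

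The procedure was tested on simulated data for AC9 against VECTOR with 19505 genes. Of 50 genes changed at each size, it recovered 58% at a log2 change of 0.5, 98% at 1, 100% at 1.5 and 100% at 2, with 12 false calls. It made 0 calls when nothing was changed. On simulated lists of 30 genes, it called 5 of 5 lists shifted by 0.3 and 0 of the others. The simulated noise was independent between genes and the lists were drawn at random. This run therefore cannot show how often the set test calls falsely where members of a list vary together.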

Results

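Transcript levels were measured on 6 arrays in 393P cells, a line derived from a mouse lung adenocarcinoma, with stable AC9 or empty-vector transfection (3 arrays each). The labels frame the comparison as the effect of AC9 overexpression on expression. They do not expand AC9, which the reference gene table lists as a synonym of Adcy9, the gene of adenylyl cyclase 9, an enzyme that makes cAMP. Neither the selection drug of each group nor the origin of its 3 samples is given in the sources used here. A difference of drug, or between the selected cells, therefore cannot be told apart from AC9 in any result below. The median log2 intensity of the genes was 6.42 to 6.46 per array, and 53.6% to 55.3% of genes per array lay above the bound from the negative controls. Correlations across genes were 0.994 to 0.996 between arrays of a group and 0.985 to 0.988 between arrays of different groups; genes are not independent replicates.

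Adcy9 (probe set TC1600001124.mm.2) was higher in the AC9 cells, at a log2 intensity of 6.73 ± 0.12 against 6.12 ± 0.03 in VECTOR (SD, n = 3). The arrays read 6.78, 6.60 and 6.82 in AC9 and 6.12, 6.09 and 6.15 in VECTOR. The log2 change was 0.61 (SE 0.10), or 1.53-fold, with a limma adjusted p of 0.00264. The VECTOR mean lay only just above the bound of 6.06 from the negative controls, so the fold may be too small. Adcy9 ranked 519 of 19505 genes from the largest rise downward, and 1199 by the size of the change in either direction. Whether the probe set reads the introduced sequence is not given in the sources used here. Of the other 9 genes of the Adcy family measured, 0 passed the limma threshold (1 at an unadjusted p under 0.05), but 8 of them lay under the bound from the negative controls in both groups.

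All 32 measured genes of the G2/M cell cycle list were higher in the AC9 cells, and several were among the genes that rose furthest. Csn3, the milk protein kappa-casein, rose at least 2.92-fold (adjusted p 2.22e-06), a lower limit because its VECTOR level of 4.69 was under the bound from the negative controls. Kif11, the kinesin that separates spindle poles, rose 5.22-fold (SE 0.12 on the log2 scale, adjusted p 7.48e-06). Aspm, a spindle pole protein, rose at least 2.83-fold (adjusted p 9.91e-06), the checkpoint kinase Bub1 4.42-fold, Prr11 4.35-fold and the proliferation antigen Mki67 4.35-fold. The kinetochore motor Cenpe rose 4.26-fold, the mitotic kinase Pbk 4.23-fold, the cyclin Ccna2 4.21-fold, the kinesin Kif2c 4.18-fold, Depdc1a 4.13-fold and Sgo1, a protector of centromeric cohesion, 3.81-fold.

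In the other direction, Rasl11a, a Ras-like GTPase, had a log2 change of -3.26 (SE 0.10, adjusted p 1.39e-06), a 9.58-fold difference, and Grhl3, an epithelial transcription factor, had -2.97 (SE 0.13, adjusted p 3.15e-06). Sptssb, a subunit of serine palmitoyltransferase, changed by -2.95 and the glutathione transferase Mgst1 by -2.90. The transcription factor Atoh8 changed by -2.60 (SE 0.09, adjusted p 1.39e-06), while Elfn1 was at least 4.44-fold lower, Islr at least 3.40-fold and the semaphorin Sema3d at least 2.82-fold (adjusted p 2.54e-06, 3.85e-05 and 5.02e-06). Antxr1 changed by -2.26, the metalloprotease inhibitor Timp3 by -2.23 (adjusted p 3.15e-06), R3hdml by -2.19 and the transcription factor Hes6 by -2.08. In Csn3, Aspm, Elfn1, Islr and Sema3d, the lower group lay under the bound from the negative controls. So did that of Pole, Etv1, Crb3, Cxcl10 and Xaf1, described with their lists. For these 10 genes the fold is a lower limit, the brighter group over the bound of each array of the dimmer group, or over the gene's own value where that was higher. In Syt11, Ifit1, Cd52 and Tie1 both groups lay under it, and no size of change is given for them. Across all genes named, standard errors were 0.09 to 0.21 on the log2 scale.

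**Figure D1:**
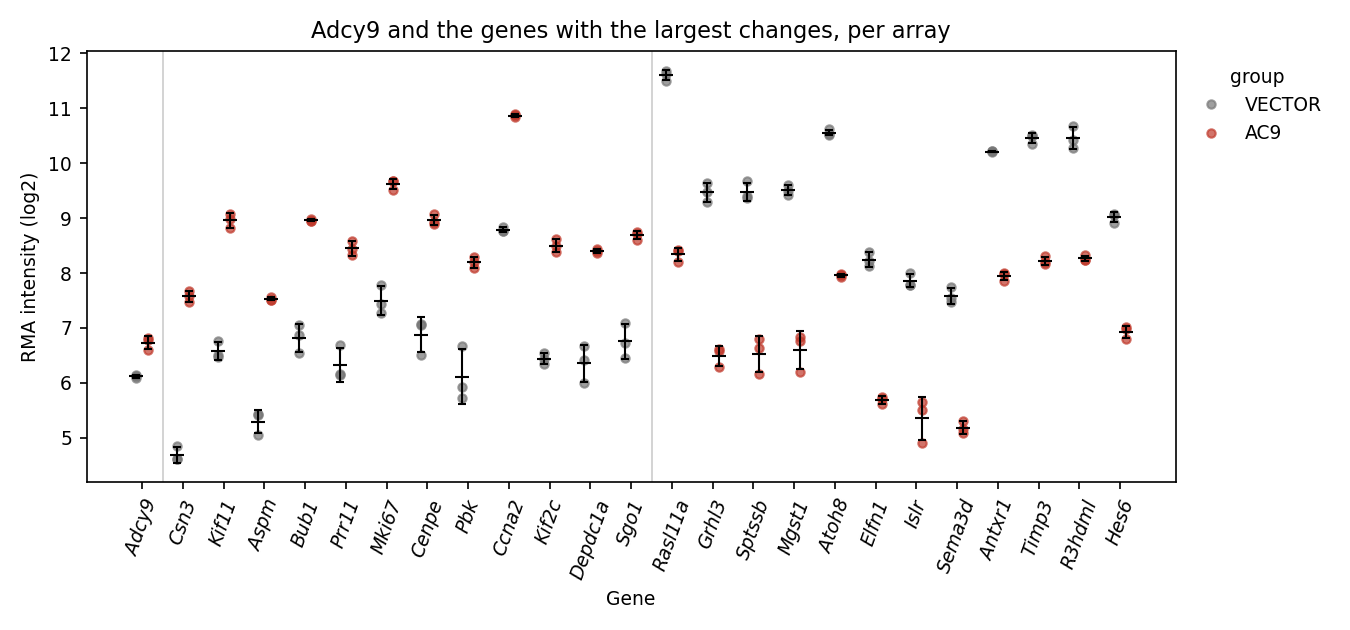
Log2 RMA intensity of Adcy9 and of the 12 genes with the largest rise and the 12 with the largest fall under the naming rule, for each of the 3 VECTOR (grey) and 3 AC9 (red) arrays; bars give the mean ± SD. The groups do not overlap for any gene shown, and Rasl11a goes from 11.60 in VECTOR to 8.34 in AC9.

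In all, 3424 of 19505 genes (17.6%) passed an adjusted p of 0.05, of which 1612 were higher and 1812 lower in AC9. A change of at least 2-fold on top of that was met by 335 genes, 139 higher and 196 lower. The groups did not overlap for 6844 genes (35.1%), against 10% by chance. With each array centred on its median, the larger share was higher instead, 1861 against 1650. Without AC9 replicate 1, the number past the threshold was 2174 (968 higher and 1206 lower), and without AC9 replicate 3 the number higher was 1061.

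All 32 measured members of the G2/M cell cycle list rose, and 32 did when adjusted over the list alone. The median log2 change was 1.58, or 2.99-fold, led by Kif11, Bub1, Mki67 and Cenpe, and the camera adjusted p was 2.52e-38 (adjusted p = 0.0518 with an estimated correlation). The mean level of the list was 7.26, 7.29 and 7.44 on the VECTOR arrays and 8.91, 8.89 and 8.92 on the AC9 arrays. In the list of DNA replication and S phase, 10 of 33 members rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.04 and an adjusted p of 0.0336 (adjusted p = 0.213 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 0.79, the replication factor Mcm10 by 0.72, Gins1 by 0.59 and Pole at least 1.21-fold (adjusted p 0.0109). The S-phase call was lost without VECTOR replicate 2 (adjusted p 0.0593) and without AC9 replicate 1 (0.0522), and with dim genes left out (0.0511).

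Of 26 p53 target genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.16 and an adjusted p of 0.0356 (adjusted p = 0.671 with an estimated correlation). Plk2 rose by 1.41, while Ckap2 and Gtse1, which also act in mitosis, rose by 1.00 and 0.86; Phlda3 had a change of -1.12. The call was lost without VECTOR replicate 1 (adjusted p 0.0790), VECTOR replicate 2 (0.0875) or AC9 replicate 2 (0.0543), and with dim genes left out (0.0511).

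In the unfolded protein and amino acid stress response, 11 of 32 members rose and 2 fell (16 and 2 adjusted over the list alone). The median was 0.27 and the adjusted p 3.34e-05 (adjusted p = 0.213 with an estimated correlation). The endoplasmic reticulum chaperones Hsp90b1 and Hspa5 rose by 0.65 and 0.56, the cysteine-forming enzyme Cth by 0.63 and the transcription factor Xbp1 by 0.57. In the list of ERK pathway feedback and output, 8 of 25 members rose and 2 fell (12 and 2 adjusted over the list alone), with a median of 0.25 and an adjusted p of 0.00563 (adjusted p = 0.388 with an estimated correlation). The cytokine Lif rose by 1.39, the growth factor Hbegf by 1.21 and the transcription factor Egr1 by 0.69, and the transcription factor Etv1 was at least 1.60-fold lower (adjusted p 7.67e-05).

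Of 19 cholesterol synthesis genes, 10 fell and 0 rose (13 and 1 adjusted over the list alone), with a median of -0.39 and an adjusted p of 0.000101 (adjusted p = 0.213 with an estimated correlation). The sterol enzymes Dhcr7, Nsdhl and Fdps changed by -0.82, -0.73 and -0.63, and Insig1, a regulator of the pathway, by -0.60. Oxidative phosphorylation had 5 lower and 1 higher of 33 (6 and 1 adjusted over the list alone), with a median of -0.14 and an adjusted p of 0.0336 (adjusted p = 0.213 with an estimated correlation). The complex subunits Ndufa4, Ndufa9 and Ndufb10 changed by -0.47, -0.43 and -0.42, while Cycs, cytochrome c, rose by 0.45. Ndufb10 lost its call without AC9 replicate 1 (adjusted p 0.0616) or AC9 replicate 2 (0.0590), and the list lost its call without VECTOR replicate 1 (0.0557) and with dim genes left out (0.108). In MHC class I antigen presentation, 4 of 18 fell and 1 rose (4 and 1 adjusted over the list alone), with a median of -0.17 and an adjusted p of 0.0356 (adjusted p = 0.213 with an estimated correlation). The peptide transporter Tap2 changed by -0.64, Tapbp by -0.58, the proteasome activator Psme1 by -0.57 and H2-T23 by -0.54. Tap2 lost its call without AC9 replicate 2 (adjusted p 0.0596). H2-T23 lost its call without any of VECTOR replicates 1, 2 and 3 (0.104, 0.0740, 0.0572) or AC9 replicates 1 and 2 (0.0883, 0.0632). The MHC list lost its call without VECTOR replicate 1 (0.0557), VECTOR replicate 3 (0.0574) or AC9 replicate 3 (0.0558), and with dim genes left out (0.111). Background probe sets read lower in AC9 as well: 19 of the 23 classes by GC content were lower without overlap, by up to a log2 difference of -0.50 in class 25 (6.80 ± 0.17 against 7.30 ± 0.24, SD, n = 3). The medians of the cholesterol, oxidative phosphorylation and MHC lists, -0.39, -0.14 and -0.17, ran the same way and were smaller in size than that largest shift. Whether the background shift contributed to the calls of these lists was not tested.

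**Figure D2:**
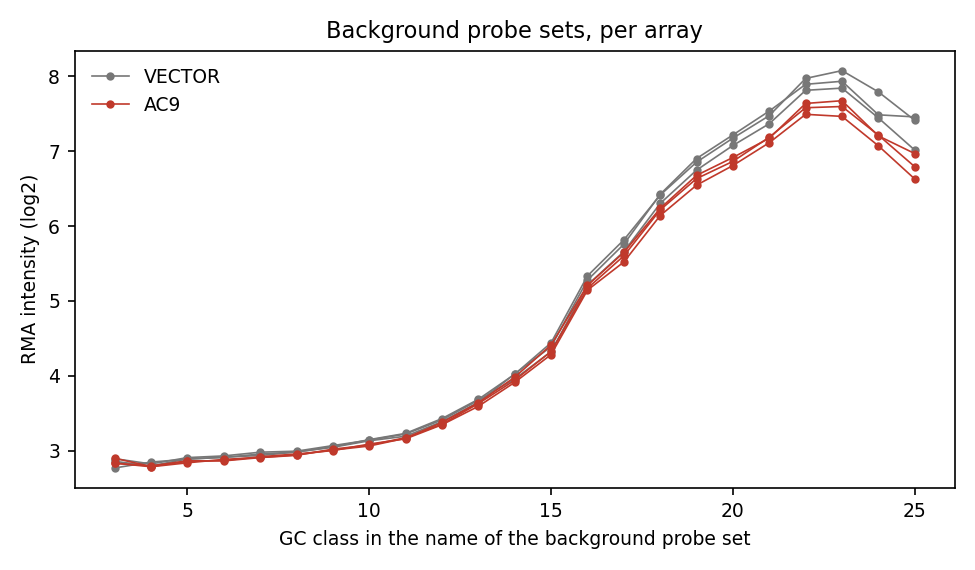
Log2 RMA intensity of the 23 background probe sets against the GC class in their names, 1 line per array (VECTOR grey, AC9 red). From class 16 upward every AC9 array lies under every VECTOR array.

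The lists of cAMP signalling components and CREB-responsive genes did not pass the set test with camera. Among 43 cAMP signalling components, 2 were higher and 5 lower (2 and 6 adjusted over the list alone), with a median of 0.07 and an adjusted p of 0.932; fry, which does not compare a list with other genes, put its direction downward. The phosphodiesterase Pde3b rose by 0.82, and the protein kinase A subunits Prkar2b and Prkaca changed by -0.71 and -0.56. Pde7b changed by -0.58 and lost its call without VECTOR replicate 3 (adjusted p 0.0651), AC9 replicate 1 (0.0819) or AC9 replicate 3 (0.106). Among 31 CREB-responsive genes, 5 were higher and 2 lower (5 and 2 adjusted over the list alone; median 0.000627, camera adjusted p 0.548). With fry the CREB-responsive list passed, upward (fry adjusted p 0.0352), as did 15 of the 25 lists in all. Ccna2, also in the G2/M list, rose by 2.07, Inhba by 0.94 and Egr1 by 0.69, and Id1 changed by -1.03.

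Epithelial and mesenchymal genes moved in both directions. Of 40 epithelial genes, 7 rose and 7 fell (7 and 9 adjusted over the list alone; median -0.05, adjusted p 0.670). The desmosomal protein Dsp rose by 0.89, while the polarity protein Crb3 was at least 1.66-fold lower (adjusted p 0.00355), and the junction protein Jup changed by -0.88 and the protease inhibitor Spint1 by -0.71. Of 32 mesenchymal genes, 2 rose and 5 fell (2 and 5 adjusted over the list alone; median -0.04, adjusted p 0.478). Zeb1, a repressor of epithelial genes, rose 2.20-fold (log2 change 1.14, adjusted p 6.95e-05), while Msrb3 changed by -1.43, the matrix protein Tnc by -1.03 and S100a4 by -0.93. Among 36 integrin and focal adhesion genes, 7 rose and 5 fell (7 and 6 adjusted over the list alone; median 0.03, adjusted p 0.712). Itga2 rose by 1.29, Fermt1 by 1.11 and Parvb by 0.82, and Fermt2 changed by -0.73.

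In the matrix lists, 3 of 38 genes of collagens, laminins and their modifying enzymes rose and 5 fell (4 and 5 adjusted over the list alone; median 0.11, adjusted p 0.670). P4ha3 changed by -1.19, Lamb2 by -0.86 and Loxl3 by -0.70, and Lamc1 rose by 0.68. Of 37 matrix proteases and inhibitors, 4 rose and 8 fell (4 and 8 adjusted over the list alone; median -0.05, adjusted p 0.463), with Timp3 lowest, then Mmp13 at -0.76, Plat at -0.74 and Adam10 at -0.72. Of 40 Golgi and secretory traffic genes, 2 rose and 7 fell (4 and 7 adjusted over the list alone; median 0.03, adjusted p 0.712). Kif20a, a motor that also serves cell division, rose by 1.63 and the coat protein Sec24d by 0.82, and Rab27a changed by -0.96. Syt11 was called but lay under the negative-control bound in both groups.

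Detoxification genes split: of 32 in the NRF2 list, 7 rose and 11 fell (8 and 12 adjusted over the list alone; median -0.05, adjusted p 0.164). Aldh3a1 changed by -1.81, the glutathione transferases Gsta4 and Gstm2 by -1.42 and -1.38, and Cyp1b1 by -1.25. Here too the rule named the largest changes by size, all of them falls, while the 7 members that rose changed less. Of 28 YAP and TGF-beta responsive genes, 7 rose and 10 fell (9 and 12 adjusted over the list alone; median -0.01, adjusted p 0.463). Id3 changed by -1.57, Bmp4 by -1.54, Smad6 by -1.14 and Id2 by -1.10. The naming rule took these 4 by size, and the 7 members that rose changed less, so the named genes do not stand for the list. Of 34 hypoxia and glycolysis genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone; median 0.04, adjusted p 0.670). Vegfa and Hk2 rose by 0.70 and 0.64, and Aldoc and Egln3 changed by -1.55 and -0.93.

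Of 37 cytokines, chemokines and NF-kB targets, 5 rose and 9 fell (7 and 9 adjusted over the list alone; median -0.02, adjusted p 0.487). The prostaglandin synthase Ptgs2 rose by 1.45 and Lif by 1.39, and Il33 and Cxcl15 changed by -1.62 and -1.37. Of 33 interferon-stimulated genes, 4 rose and 4 fell (4 and 8 adjusted over the list alone; adjusted p 0.670), and the median of 0.000129 and the mean of -0.03 differed in sign. Cxcl10 rose at least 1.14-fold (adjusted p 0.00270), Xaf1 was at least 1.22-fold lower (adjusted p 0.00818), Irf9 changed by -0.68, and Ifit1 was called but under the negative-control bound in both groups. Of 34 lung lineage genes, 4 rose and 7 fell (4 and 9 adjusted over the list alone; median -0.08, adjusted p 0.463). The water channel Aqp5 changed by -1.45 and Cxcl15 by -1.37, and Sox9 and Hmga2 rose by 0.88 and 0.83.

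Of 15 leukocyte markers, 2 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.04, adjusted p 0.436), and Cd14 rose by 0.91. The other, Cd52, lay under the negative-control bound in both groups and lost its call whichever array was left out (adjusted p 0.0526 to 0.124). Of 16 markers of endothelium and fibroblasts, 0 passed (0 adjusted over the list alone; median 0.03, adjusted p 0.712), with Tie1 under the negative-control bound in both groups (adjusted p 0.0547) and Esam at -0.30 (0.0665). Of 28 ribosomal protein genes, 0 rose and 1 fell (0 and 0 adjusted over the list alone; median -0.03, adjusted p 0.613). That gene, Rplp0, changed by -0.31 and lost its call whichever array was left out (adjusted p 0.0652 to 0.109).

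**Figure D3:**
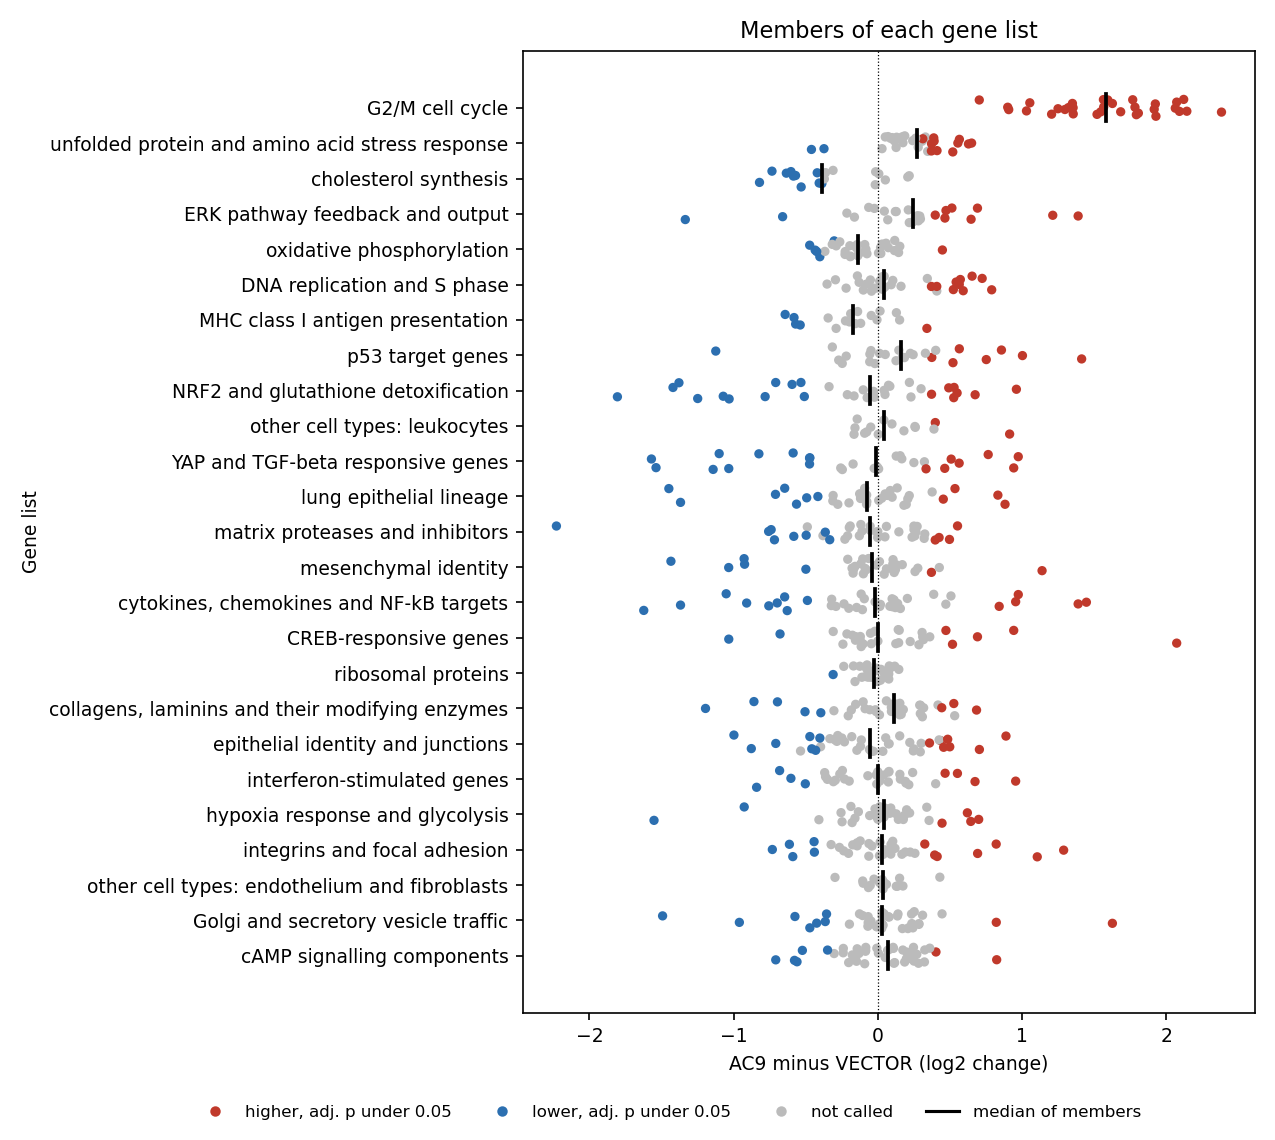
Log2 change (AC9 minus VECTOR) of each measured member of the 25 gene lists, ordered by the camera p; points are members (red higher, blue lower, both at an adjusted p under 0.05, grey not called) and black bars are medians. The G2/M list stands at a median of 1.58 with all 32 members higher.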

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

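The tests of the background, of S phase and of the growth state were chosen only after the G2/M result was seen, whereas those over other splits of the arrays were planned.

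Among the probe sets left out of the comparison for want of a gene name here, 149 of 2634 were higher in AC9 and 126 lower by limma at an adjusted p of 0.05, a signal in data outside the main measurement. Likewise, 19 of the 23 background probe sets, which are meant to match no transcript, differed between the groups without overlap, all lower in AC9, where 10% would do so in either direction by chance.

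For the rise of the G2/M list, with 32 of 32 members higher, the shift of the background probe sets with GC content reached 0.498 and ran downward. The lower quartile of the members' log2 change was 1.32. A shift of the size and direction seen in the background would not give this rise. The GC content of the genes' own probes was not available, so another effect of GC content on them stays open. An equal rise of S-phase and G2/M transcripts is argued against by the upper quartile of the S-phase list, 0.41, under 0.79, which is 50% of the G2/M median. Histone genes, most of them S-phase transcripts, rose further, with an upper quartile of 0.82, over that mark but under the G2/M lower quartile. A smaller rise was thus seen in part of the S-phase transcripts: 49 of 52 histone genes and 10 of 33 members of the S-phase list were called higher, and 0 of either lower. A different density or growth state of the cultures could give the same pattern and cannot be told apart from AC9: the lowest AC9 array mean exceeded the highest VECTOR array mean by 1.46, but the labels do not give the state of the cultures. An effect of AC9 on the cell cycle stays open, as untested.

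The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The count of genes was 3424 in the real split and at most 0 in the others, with 1 split as large, the real one. The count with a 2-fold change was 335 and at most 0, again with 1 split as large. The count of gene lists was 8 and at most 5, also with 1 split as large. The set test at its preset correlation called 1 to 5 lists in the other splits. Each of the other splits, however, put arrays of both groups on both sides. The real difference then widened the spread within a side and partly remained between the sides. Low gene counts there were thus built in, and the lists called there need not be false calls. The comparison with these splits therefore decides nothing.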

How the results depend on the processing

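Leaving the G2/M genes out of the other lists was chosen only after the result was seen and gave 8 lists. The G2/M list shared only Ccna2, with the CREB-responsive list, and Kif20a, with the Golgi list. Neither of those lists was called, so no other called list lost a member and the unchanged count decides nothing. Adcy9 kept its direction and call in every alternative run, with log2 changes from 0.57 to 0.68, and no list or named gene called as reported reversed. The 3424 genes became 1670 at an adjusted p of 0.01, by construction, and 2174 to 3025 with 1 array left out, lowest without AC9 replicate 1; 1856 genes (54.2%) were called in all 6 such fits. With median centring, 1861 of 3511 were higher in AC9; in the other settings the higher share was 43.7% to 49.3%. The 335 genes with a 2-fold change became 1323 at 1.5-fold, by construction, and 311 to 380 with 1 array left out. The 8 lists became 4 without dim genes, 4 at an adjusted p of 0.01, 0 with an estimated correlation, 15 with fry, which does not compare a list with other genes, and 5 to 7 with 1 array left out, lowest without VECTOR replicate 1; beyond the threshold and the number of arrays, the cause was not tested. Over 448 settings of the lists, 416 kept their side of the threshold, 25 lost the call and 7 gained it; for 108 named genes other than Adcy9, 1574 of 1616 did, 38 lost it and 4 gained it. Signal over background limits the dim genes: 10600 of 19505 had a mean above the bound of 6.06.

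With the replicate number as a block (replicate block), 3062 genes passed, 2909 of them among the 3424, with 335 at 2-fold, 8 lists and Adcy9 at 0.61 (adjusted p 0.00669; 0.000688 to 0.0153 over its alternatives). Deviations of same-numbered arrays correlated at 0.01, 0.08 and 0.01 across genes, none over 0.1, so the samples were taken to share only a number. AC9 replicates 2 and 3 correlated best with the VECTOR array of their own number and AC9 replicate 1 with VECTOR replicate 3.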

Other observations

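The tests of histone genes, of symbol families and of chromosomes were chosen only after the result was seen, and the further BMP targets were written down before their values were looked at.

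Histone genes rose nearly throughout. Of 52 genes with linker or core histone symbols above the bound from the negative controls, 49 were higher in AC9 and 0 lower, with a median log2 change of 0.63 (camera p 2.22e-30, p = 0.000147 with an estimated correlation). H1f1, a linker histone chosen after its value was seen, rose the most, by 1.44. Near-identical histone genes can share probes, so these are not 52 independent measurements. Among 172 families of genes sharing a symbol stem, kinesins (Kif) had 12 of 23 higher and 0 lower (camera adjusted p 2.21e-05, adjusted p = 0.879 with an estimated correlation). Of these kinesins, 4 belong to the G2/M list, and without them 8 of 19 were higher (adjusted p 0.0110). Nucleoporins (Nup) had 5 of 16 higher and 0 lower (adjusted p 0.00908, adjusted p = 0.879 with an estimated correlation), and centrosomal proteins (Cep) 10 of 27 higher and 1 lower (adjusted p 0.0262, adjusted p = 0.879 with an estimated correlation), so none of these 3 calls held with an estimated correlation.

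The chromosome tests used the 10576 genes above the bound from the negative controls whose chromosome in the probe set name matched the gene table. Among these, genes of chromosome 18 were shifted upward in AC9: the median log2 change of 245 genes was 0.21, and 77.1% lay above 0 (camera adjusted p 5.87e-07, adjusted p = 0.384 with an estimated correlation). The AC9 arrays stood at 0.15, 0.14 and 0.14 relative to the mean of the 10576 genes, and the VECTOR arrays at -0.10, -0.10 and -0.04. Across these genes, the change correlated with log2 local gene density at -0.23 (Spearman). A correction for density and level left a median of 0.16 (bootstrap SE 0.02), which argues against density itself as the whole cause. Density only stands in for the GC content of the probes, which was not available. A trend with GC content therefore stays open for chromosome 18. Extra copies of this chromosome, or of chromosome 13, in some of the AC9 cells stay open as untested: on 18, 100% of the blocks of 20 neighbouring genes lay above the median of the 10576 genes, but with the genes in random order 99.9% did on average, so the blocks decide nothing, and the shift is under the 0.58 of 3 copies over 2. Other chromosomes also passed camera: 13, which holds a histone cluster (median 0.15, 20 of 21 blocks above, adjusted p 1.37e-06), 1 (median 0.09, 25 of 29, 0.0189) and, in the other direction, 5 (median -0.10, 7 of 35, 0.0189), each with an adjusted p = 0.384 with an estimated correlation. The correction for density and level left medians of 0.14 on 13, 0.05 on 1 and -0.08 on 5. Chromosome 13 was not retested without its histone genes. Random orders were run only for 18, so the block counts of the others decide nothing. DNA was not analysed here.

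Lower BMP-SMAD signalling was a hypothesis from Atoh8 (-2.60), Id3 (-1.57), Bmp4 (-1.54), Smad6 (-1.14), Id2 (-1.10) and Id1 (-1.03), known targets or a ligand of that pathway. Of 16 further targets, 14 were measured, 2 were lower (Bmper at -1.46 and Smad9, which was under the bound from the negative controls in both groups, both singled out after their values were seen) and 0 higher, with a median of -0.10 and a camera p of 0.158 (p = 0.342 with an estimated correlation), but 10 of the 14 were under that bound already in VECTOR and could hardly show a fall, so this test decides nothing and the hypothesis stays open. Smad7, another target chosen after its value was seen, was at 0.16 (limma adjusted p 0.398).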
